A study of Homo sapiens with 6 samples.

How the data were processed

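RNA-seq libraries of total RNA came from H9, an established human embryonic stem cell line, in 2 culture systems with 3 libraries each. Groups were read from the submitters' source labels, which name undifferentiated feeder-free cells and stem-cell-derived amnion-like cells. The series design calls the 3 libraries of each system biological replicates. Replicates were numbered in accession order, so a number names a library and pairs nothing.

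The deposited table held whole-number read counts for 23187 gene symbols in the 6 libraries, which the authors labelled as raw reads per the file headers. Of these symbols, 2602 had no read in any library, 0 were duplicated and 0 were summary rows. The submitters' processing notes name STAR, HTSeq, edgeR and the hg19 build, without their settings. HTSeq counts reads per gene, and whether strand was used is not given in the sources used here, so antisense and overlapping genes could not be separated from their partners. The same table held the authors' log2 fold change of gel culture over maintenance culture, its linear fold as a ratio, and a p-value and false discovery rate per gene, per the file headers. These deposited result columns were used only for a comparison with the counts beside them.

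The file gives gene symbols without positions, so no coordinates are printed. Against RefSeq symbols of the GRCh38.p14 assembly, 20695 symbols matched a current name and 1712 matched only an older synonym. Genes are named as the table gives them.

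Library totals ran from 22048775 to 28757203 counts. In a library, 3 reads corresponded to 0.1043 to 0.1361 CPM (counts scaled to a common library total). For a group in which all 3 libraries had 0 reads, a fold was given as a lower bound against the floor of 3 counts per library. Where a group had 1 to 3 reads in total, the ratio of summed counts was given with an exact binomial 95% interval. Fitted log2 fold changes of such genes depend on edgeR's prior count and are no bounds. Bounds and intervals cover counting error only, because reads without molecular identifiers are not independent molecules.

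Counts were fitted with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, libraries were scaled with TMM (trimmed mean of M values), and the groups were compared with the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences of at least 2-fold were tested with glmTreat. The standard error of a log2 fold change was its size divided by the square root of F. CPM values used TMM-scaled library sizes and are given as mean ± SD with n = 3. Library-wide measures were compared with a two-sided exact permutation test, which cannot go below 0.1 with 3 libraries against 3.

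Gene lists were fixed before the data were examined, 23 by name and 15 gene families by symbol pattern. Each was tested with camera from limma 3.58.1, which ranks a list's members against all other tested genes, with a preset inter-gene correlation of 0.01 and again with an estimated correlation. Each was also tested with fry, a rotation test of whether a list's members changed, without comparing them with other genes. Adjustment ran over the 37 lists and families with tested members. The family of genes on the mitochondrial genome had 0 symbols in the table.

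Genes were named by a rule fixed before the data were examined. The first part took the 12 largest positive and 12 largest negative log2 fold changes among genes past the threshold, with an average log2 CPM of at least 2 and non-overlapping libraries. Transcripts with LOC, LINC, MIR, SNOR or clone names were counted, not named, and made up 125 of the 7646 eligible genes. The second part named 20 lineage and signalling genes whatever their value. The third part took up to 4 members of each list or family with the smallest adjusted p. Other genes named in the text were chosen after their values were seen.

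The fit was tested on simulated counts with the feeder-free means and the real library sizes and 200 changed genes. At the threshold of 0.05 it recovered 13.4% of 1.5-fold changes, 83.6% of 2-fold changes and 93.9% of 4-fold changes. It made 7 false calls among 15798 unchanged genes, with 15992 genes tested. Simulated genes varied independently, so this number does not cover shifts that many genes of a library share. The alternatives were other scaling factors, other low-count filters, DESeq2 1.42.0, limma-voom, a robust quasi-likelihood fit, an adjusted p threshold of 0.01, and each library left out in turn. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.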

Results

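The series asked how H9 embryonic stem cells in a soft, matrix-rich niche differ from the same cells in conventional maintenance culture. Total RNA was sequenced on day 5 from 3 feeder-free cultures, grown on glass with a thin coat of 1% Geltrex, a basement membrane extract. It was also sequenced from 3 gel-3D cultures, in which a Geltrex bed over 100 µm deep carried the cells and 4% Geltrex went into the medium each day from day 1. Both systems used mTeSR1, a defined stem cell medium, with 30000 cells seeded per square centimetre and 10 µM Y27632, a kinase inhibitor, for the first 24 h. The submitters describe the gel-3D cells as squamous amnion-like cells. The feeder-free libraries 1, 2 and 3 held 25095875, 23914180 and 23099591 counts, and the gel-3D libraries held 28757203, 22589036 and 22048775 (two-sided exact permutation p = 1.0).

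Gel-3D cells switched on the transcription factors HAND1, ISL1, TBX3, GATA3, TFAP2A and CDX2 and raised BMP target genes, while POU5F1 stayed near its feeder-free level and SOX2 fell. Of 16257 genes tested, 4822 were higher and 4843 lower in gel-3D, 59.5% of all (edgeR quasi-likelihood, adjusted p under 0.05). A difference of at least 2-fold was called for 728 higher and 1404 lower genes. The groups did not overlap in 11050 genes, 68% of those tested, where chance gives 10%. The balance of directions depended on the scaling: 3720 genes were higher and 5806 lower with upper-quartile factors, and 3527 higher and 5994 lower with library size alone. These scalings moved the median log2 fold change of all genes from -0.002 to -0.141 and -0.165.

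The gel-3D libraries were not equally far from the feeder-free libraries. On the first principal component, which carried 88.9% of the variance, feeder-free libraries lay at -71.3, -80.4 and -80.2, and gel-3D libraries 1, 2 and 3 at 58.2, 69.8 and 103.9. Gel-3D replicate 3 had the highest gel-3D value for 3206 of the 4822 higher genes and the lowest for 3021 of the 4843 lower genes. Gel-3D libraries had fewer genes detected, 18655 ± 203 against 19100 ± 178 (mean ± SD, n = 3; exact permutation p = 0.1, the smallest possible). The 10 most abundant genes took 4.53% ± 0.007 of gel-3D counts and 4.07% ± 0.315 of feeder-free counts (SD, n = 3; exact permutation p = 0.1). MTRNR2L genes, nuclear copies that share reads with mitochondrial ribosomal RNA, took 0.276% ± 0.095 and 0.998% ± 0.232 in the same order (SD, n = 3; exact permutation p = 0.1).

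**Figure D1:**
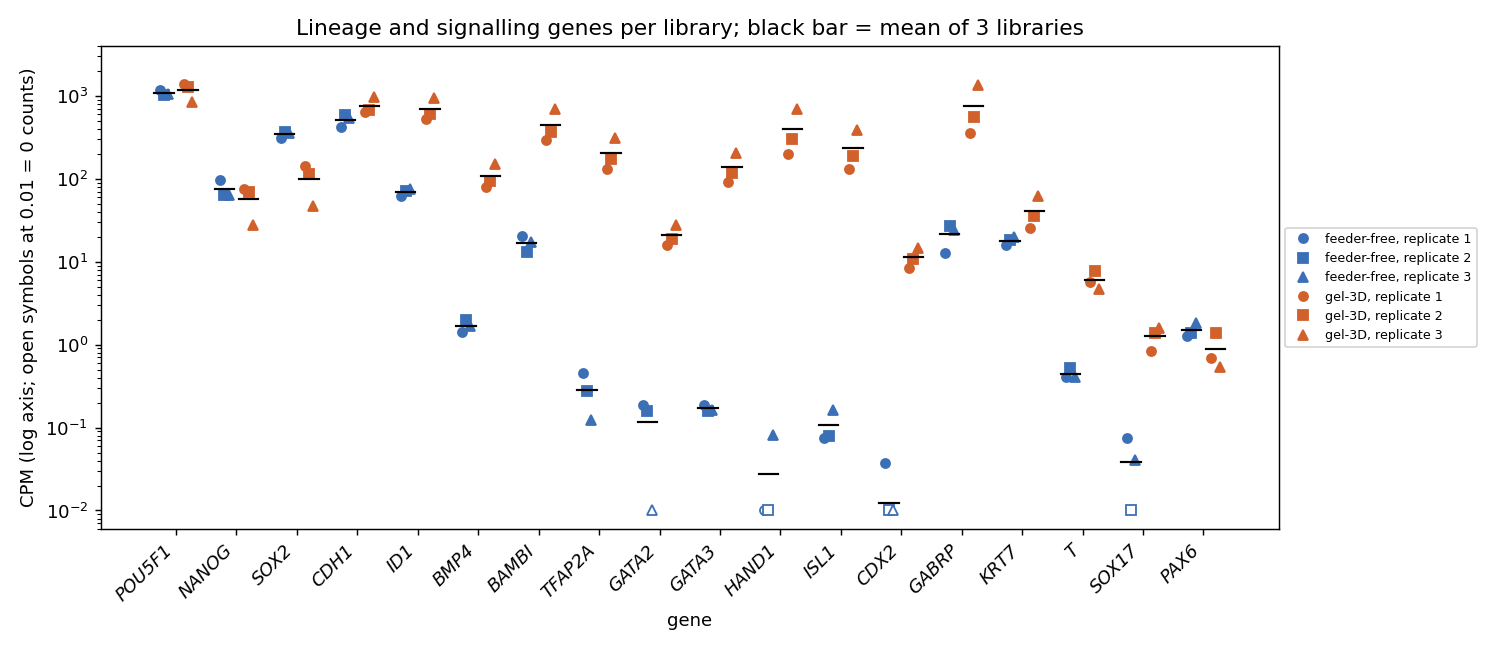
CPM of 18 lineage and signalling genes (log axis) in each of the 3 feeder-free (blue) and 3 gel-3D (orange) libraries, with black bars at the group means and open symbols for 0 reads. GATA3 lies at 0.17 CPM in feeder-free and 138 CPM in gel-3D cultures, while POU5F1 lies at 1081 and 1177 CPM.

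All 24 tested amniotic ectoderm genes rose in gel-3D. By glmTreat, 23 of them were called at least 2-fold higher, and KRT7 was not (adjusted p = 0.533). The median log2 fold change was 7.43, and the list's camera adjusted p was 4.39e-30, with an adjusted p = 0.387 with an estimated correlation and 5.11e-64 to 4.27e-10 under the other settings. GATA3, a trophectoderm and amnion transcription factor, rose from 0.170 ± 0.0149 to 138 ± 58.8 CPM, 785-fold (log2 9.62 ± 0.46 SE, edgeR adjusted p = 2.23e-05). TFAP2A rose from 0.284 ± 0.163 to 204.5 ± 93.2 CPM, ISL1 from 0.106 ± 0.0496 to 233.7 ± 132 CPM, and GATA2 from 0.116 ± 0.101 to 21.0 ± 6.20 CPM. HAND1 had 2 reads over the feeder-free libraries and 395 ± 259 CPM in gel-3D, a ratio of 14200 (95% counting interval 3940 to 118000). CDX2 had 11.3 ± 3.20 CPM in gel-3D, a ratio of 838 (150 to 33100). TFAP2B had 0 feeder-free reads and was at least 282-fold higher. Of the members named here, GABRP, CLDN10 and KRT7 had the highest feeder-free levels and the smallest rises. GABRP, a GABA receptor subunit, rose 35.1-fold to 748 ± 517 CPM, CLDN10 4.86-fold, and KRT7 2.26-fold (edgeR adjusted p = 0.0101). Whether the rise followed the feeder-free level across the list was not tested. The median was 8.48 without feeder-free replicate 1, and 6.74 over 27 genes with no low-count filter. Gel-3D replicate 3 was highest for all 24 genes, and without it the median was 6.97, GABRP's log2 fold change 4.42 rather than 5.13 and HAND1's 12.96 rather than 13.62. Without feeder-free replicate 3 the log2 value of HAND1 was 16.22, and without feeder-free replicate 1 that of CDX2 was 11.07 rather than 9.27. Each omitted library held all of the gene's feeder-free reads, so these values of HAND1 and CDX2 rest on the fit's prior count. Several members are known from earlier work on stem-cell models of amnion, so the direction of this list is not independent evidence. Several are also shared with trophoblast, so the list alone does not tell amnion from trophoblast.

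Genes of the BMP pathway rose as a group, with 15 of 17 tested members higher and 1 lower. BMP4, a ligand of the pathway, rose from 1.68 ± 0.268 to 108.6 ± 37.2 CPM, 64.4-fold. ID1, a direct SMAD target, rose 9.93-fold to 687 ± 219 CPM, and BAMBI, a decoy receptor, rose 26.5-fold to 449 ± 211 CPM. ID4, ID2 and the inhibitory SMAD6 had log2 fold changes of 4.16 ± 0.11, 2.76 ± 0.18 and 3.86 ± 0.25 (SE). The antagonist CHRDL1 fell (log2 -1.04 ± 0.17), and GREM1 had a log2 fold change of -0.13 ± 0.40 (edgeR adjusted p = 0.797). Camera's adjusted p was 4.5e-14, with 0.387 as the adjusted p with an estimated correlation and 4.99e-20 to 7.74e-06 under the other settings. Of the 15 higher genes, 14 were highest in gel-3D replicate 3.

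Pluripotency genes fell in part. Of 23 tested, 13 were lower, 2 higher and 8 did not pass, with a median log2 fold change of -0.59. By glmTreat, 5 were called at least 2-fold lower, and SOX2 was not (adjusted p = 0.0612). SOX2 was 3.40-fold lower, at 342.5 ± 28.9 CPM in feeder-free and 100.7 ± 49.1 CPM in gel-3D (edgeR adjusted p = 0.00319). FGF2 was 3.62-fold lower, and TDGF1 and SALL4 had log2 fold changes of -1.90 ± 0.31 and -0.59 ± 0.10 (SE). POU5F1 stood at 1081 ± 85.8 and 1177 ± 295 CPM (log2 0.12 ± 0.18, edgeR adjusted p = 0.574), and its estimate was 0.32 with an adjusted p of 0.0165 without gel-3D replicate 3 and -0.02 without gel-3D replicate 1. NANOG stood at 74.4 ± 19.1 and 57.5 ± 26.1 CPM (log2 -0.37 ± 0.35, edgeR adjusted p = 0.386). Gel-3D replicate 3 was lowest for 12 of the 13 lower genes, and without it 4 genes were higher. Only 1 was higher without feeder-free replicate 1 or 2 or gel-3D replicate 1 or 2. By camera the adjusted p was 0.0107, the adjusted p = 0.748 with an estimated correlation, and the range under the other settings 0.00136 to 0.0439.

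Of 10 primed epiblast genes, which mark the post-implantation-like state, 6 were lower and 1 higher. The WNT receptor FZD7 and the homeobox gene OTX2 had log2 fold changes of -2.47 ± 0.16 and -3.29 ± 0.25 (SE), and CD24 of -0.64 ± 0.09. HMX2 fell to 2 reads over the gel-3D libraries, a ratio of 52.8 (95% counting interval 14.3 to 441). The camera adjusted p was 0.0118, the adjusted p = 0.748 with an estimated correlation, and the others ran from 0.00422 to 0.065, the last under limma-voom. Gel-3D replicate 3 was lowest for all 6, and without it 3 genes were higher. The higher genes were 2 without feeder-free replicate 1 and 0 without feeder-free replicate 2 or 3, gel-3D replicate 1 or 2, or with upper-quartile factors or library size alone. Only 4 naive epiblast genes were tested, 2 higher and 1 lower (camera adjusted p = 0.608). Only 1 was higher without feeder-free replicate 2 or 3 or gel-3D replicate 1 or 2, and the lower genes were 3 without feeder-free replicate 1 and 2 without gel-3D replicate 1, 2 or 3. Those fits tested more naive genes, from 5 without feeder-free replicate 2 to 8 without gel-3D replicate 2, with 6 without feeder-free replicate 1. KLF5 rose 4.59-fold, TFCP2L1 had a log2 value of 0.39 ± 0.13, SUSD2 of -0.94 ± 0.19 and KLF4 of -0.22 ± 0.30. TFCP2L1 no longer passed without any of feeder-free replicate 2 or 3 or gel-3D replicate 1 or 2 (edgeR adjusted p of 0.103, 0.138, 0.0875 and 0.102).

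**Figure D2:**
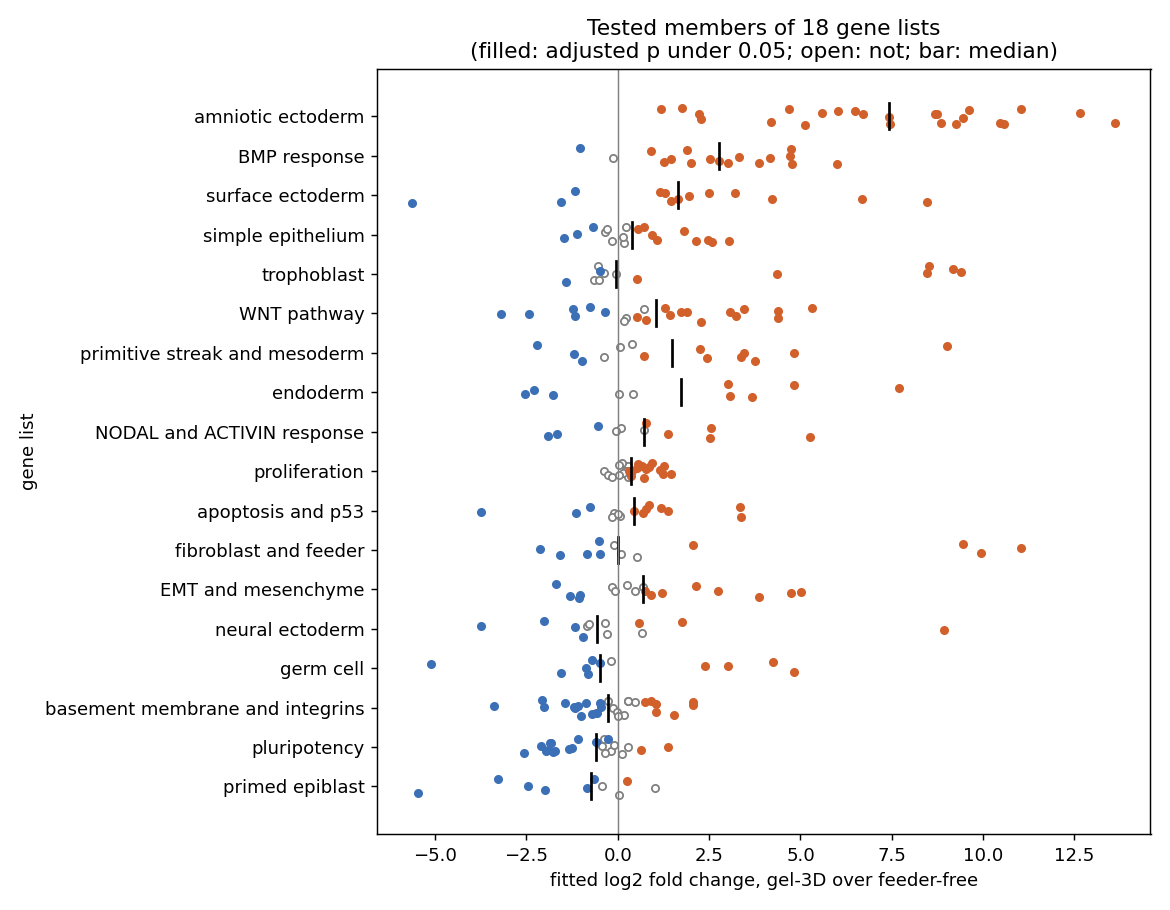
Fitted log2 fold change, gel-3D over feeder-free, of each tested member of 18 gene lists, filled where edgeR's adjusted p was under 0.05 (orange higher, blue lower), with a black bar at each median. The amniotic ectoderm list has its median at 7.43 and the pluripotency list at -0.59, and values of genes with 0 reads in a group depend on the fit's prior count.

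Keratins of simple and stratified epithelia rose. Of 17 tested family members, 15 were higher and 1, KRT222, was lower. Of the 15, 6 were pseudogenes that share sequence with KRT8, KRT16, KRT18 or KRT19, so their reads cannot be assigned with certainty, and 9 of the other 11 members rose. KRT8 rose from 202 ± 14.4 to 1665 ± 409 CPM, KRT80 9.06-fold, and KRT23 from 2 reads to 11.4 ± 2.15 CPM. Camera's adjusted p was 2.23e-12, the adjusted p = 0.468 with an estimated correlation, and the others ran from 4.38e-16 to 7.74e-06. Gel-3D replicate 3 was highest for all 15, and 2 keratins, of 18 then tested, were lower without feeder-free replicate 1.

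In the simple epithelium list 9 of 18 genes rose and 3 fell, against 7 and 5 with upper-quartile factors and 7 and 6 with library size alone. The lower genes were 5 without feeder-free replicate 1 or gel-3D replicate 3. KRT18, KRT8 and the small GTPase RAB25 rose, with log2 fold changes of 2.14 ± 0.19, 3.04 ± 0.18 and 1.80 ± 0.12 (SE), while the tight junction gene OCLN fell (-1.48 ± 0.13). CDH1, or E-cadherin, stood at 517 ± 80.1 and 764 ± 180.5 CPM (log2 0.56 ± 0.18, edgeR adjusted p = 0.0269). Its adjusted p was 0.0846 without feeder-free replicate 1 and 0.0597 without feeder-free replicate 3. The camera adjusted p of the list was 0.0178, the adjusted p = 0.748 with an estimated correlation, and the others ran from 0.0047 to 0.114, the last under limma-voom. Gel-3D replicate 3 was highest for all 9 genes that rose.

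Surface ectoderm genes rose in 10 of 13 cases and fell in 3. TP63, a regulator of stratified epithelium, rose from 0.130 ± 0.0534 to 47.7 ± 24.4 CPM, and SFN, GRHL3 and GRHL2 had log2 fold changes of 3.20 ± 0.22, 4.23 ± 0.32 and 1.65 ± 0.18 (SE). The desmosomal genes DSC3 and DSG3, named after their values were seen, were among the 3 that fell. Gel-3D replicate 3 was highest for 9 of the 10 genes that rose. By camera the adjusted p was 0.00124, the adjusted p = 0.468 with an estimated correlation, and the others ran from 2.98e-05 to 0.0414.

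Trophoblast genes split. Of 13 tested, 6 were higher and 2 lower, and the list's median log2 fold change of -0.06 differed in sign from its mean of 2.80. The median turned positive under several settings: it was 1.52 with no low-count filter, 0.17 with the stricter filter, and 0.24, 0.19 and 0.24 without feeder-free replicate 1, 2 or 3. Without gel-3D replicate 1 or 3 it was 0.23 or 0.05. All 6 higher genes were highest in gel-3D replicate 3, and 1 gene rather than 2 was lower without feeder-free replicate 2, feeder-free replicate 3 or gel-3D replicate 2. KRT23, TP63 and the iron exporter SLC40A1 rose, the last from 1 read over the feeder-free libraries to 10.6 ± 5.38 CPM, and CSF3R had a log2 fold change of 4.36 ± 0.43 (SE). No tested chorionic gonadotropin gene was called higher, and CGB5 had a log2 value of -0.51 ± 0.33. CGA had 0 reads in feeder-free libraries and 1, 2 and 2 in the gel-3D libraries, too few to be tested. With no low-count filter 9 of 23 trophoblast genes were higher and 2 lower. CGB, CGB5 and CGB8 are near-identical, so their reads are shared. The camera adjusted p was 0.0135, the adjusted p = 0.748 with an estimated correlation, and the others ran from 0.00103 to 0.344. The call was lost under DESeq2 (0.0763) and limma-voom (0.344). None of the amniotic list's members was in the trophoblast list, though several are shared with trophoblast. The lists set side by side therefore do not tell amnion from trophoblast.

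Primitive streak and mesoderm genes were higher in 8 of 14 cases and lower in 3. T (brachyury) rose 13.5-fold but reached 6.10 ± 1.56 CPM, EOMES 1.92 CPM and the receptor APLNR 10.2 CPM, while DLL3 fell (log2 -2.21 ± 0.26). Camera's adjusted p was 0.0195, the adjusted p = 0.387 with an estimated correlation, and the others ran from 0.00523 to 0.234. The call was lost under a stricter low-count filter (0.234, with 3 of 7 members higher), DESeq2 (0.0763) and limma-voom (0.114). Of 10 endoderm genes, 5 were higher and 3 lower (camera adjusted p = 0.177). SOX17 had 3 reads over the feeder-free libraries and 1.27 ± 0.382 CPM in gel-3D, a ratio of 31.1 (95% counting interval 10.3 to 154), and its log2 value went from 4.82 to 5.62 without feeder-free replicate 1. RHOBTB3 rose to 762.5 CPM (log2 3.08 ± 0.26), EPSTI1 rose too, and APOB fell (-2.53 ± 0.22). EPSTI1's log2 value of 3.67 was 2.94 without gel-3D replicate 3.

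Neural genes moved both ways, 3 higher and 4 lower of 12 (camera adjusted p = 0.706). Only 1 was higher without feeder-free replicate 1, feeder-free replicate 3 or gel-3D replicate 3, and of 14 then tested 7 were lower without gel-3D replicate 1 or 2 and 8 without gel-3D replicate 3. PAX6 stood at 1.502 ± 0.296 and 0.874 ± 0.456 CPM (log2 -0.78 ± 0.37, edgeR adjusted p = 0.105), and at -1.26 with an adjusted p of 0.0232 without gel-3D replicate 2. MEIS1 rose from 0.108 to 53.4 CPM, while SOX3 and NCAM1 fell (log2 -1.16 ± 0.17 and -0.96 ± 0.16). MEIS1's log2 value was 8.32 rather than 8.92 without feeder-free replicate 1. Of 11 germ cell genes, 4 were higher and 6 lower (camera adjusted p = 0.706). TFAP2C rose to 74.0 CPM and NANOS3 from 3 reads to 0.843 CPM, whereas DAZL was 34.6-fold lower. Only 2 germ cell genes, of 12 then tested, were lower without feeder-free replicate 2, feeder-free replicate 3 or gel-3D replicate 2.

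WNT ligands and pathway genes rose on balance. Of 13 ligands, 7 were higher and 2 lower: WNT6, named with the amniotic list too, rose from 0.0757 to 38.6 ± 19.8 CPM, WNT5B 8.41-fold, WNT3A from 0.251 to 2.82 CPM and WNT3 4.90-fold. WNT6's log2 value went from 8.85 to 10.56 without feeder-free replicate 1, and 1 ligand was lower without feeder-free replicate 2 or gel-3D replicate 2 or 3. For the ligands camera's adjusted p was 0.00654, the adjusted p = 0.468 with an estimated correlation, and the others ran from 7.92e-06 to 0.128, the last under limma-voom. In the wider WNT pathway list 13 of 22 genes rose and 6 fell. The transcription factors SP5 and LEF1 and the receptor-clearing ligase RNF43 had log2 fold changes of 5.32 ± 0.35, 4.39 ± 0.31 and 3.25 ± 0.28 (SE). AXIN2, a widely used WNT target, fell (-1.16 ± 0.11), as did the secreted inhibitor SFRP1, from 1120 to 208 CPM; these 2 genes were chosen after their values were seen. The list's camera adjusted p was 0.0112, the adjusted p = 0.387 with an estimated correlation, and the others ran from 0.00444 to 0.0904, the last under limma-voom.

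In the family labelled FGF ligands, 5 of 9 tested genes were lower and 1 higher. Its symbol pattern also took in FGF11, FGF12 and FGF13, which are not secreted ligands. FGF2, FGF19 and FGF21 fell, with log2 fold changes of -1.85 ± 0.11, -2.70 ± 0.43 and -4.84 ± 0.37 (SE), and FGF13 rose (0.93 ± 0.10). By camera the adjusted p was 0.0477, the adjusted p = 0.554 with an estimated correlation, and the others ran from 0.0232 to 0.108, with 0.0555 without feeder-free replicate 1. NODAL and ACTIVIN genes moved both ways, 5 higher and 3 lower of 11 (camera adjusted p = 0.361). LEFTY2 and the inhibitory SMAD7 rose (2.55 ± 0.29 and 2.53 ± 0.25), and FOXH1 fell (-1.67 ± 0.22). Only 3 were higher without feeder-free replicate 1, feeder-free replicate 2 or gel-3D replicate 2.

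HOX genes, which pattern the trunk, went from near silence to low expression. All 11 tested members rose, with a summed level of 0.104 CPM in feeder-free and 38.8 CPM in gel-3D cultures. HOXB2 made up 19.4 ± 13.8 CPM, HOXB3 4.85 ± 2.76 CPM, HOXB9 3.47 ± 0.247 CPM (at least 29.4-fold higher than 0 reads) and HOXC4 2.22 ± 0.310 CPM. The median log2 fold change was 7.74, or 4.44 with genes at 0 set to their bound, and 5.76 with no low-count filter, 9.37 with the stricter filter and 6.28 under limma-voom. Camera gave an adjusted p of 1.88e-09, the adjusted p = 0.387 with an estimated correlation, and the others ran from 1.37e-11 to 0.000318. The low-count filter set how many were tested: 28 of 37 rose with no filter, and 3 of 3 with the stricter filter. No tested member had more than 2 reads in any feeder-free library. Each passed the filter through its gel-3D counts, which fixed the direction of the 11 calls and of camera's result.

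Collagen genes were mostly lower, 22 of 41 against 6 higher. COL12A1, COL23A1 and the basement membrane chain COL4A1 were 17.5-, 4.77- and 2.70-fold lower, while COL3A1 rose from 0.0649 to 70.0 ± 55.7 CPM. The camera adjusted p was 0.00978, the adjusted p = 0.748 with an estimated correlation, and the others ran from 1.82e-05 to 0.0435. Basement membrane and integrin genes showed 7 higher and 13 lower of 29 (camera adjusted p = 0.292), with ITGA1, LAMA3 and COL4A2 lower (log2 -2.07 ± 0.24, -3.40 ± 0.32 and -1.02 ± 0.13). In the integrin family, which by its symbol pattern also took in integrin-binding proteins, 6 of 26 were higher and 11 lower (0.196). ITGB6, an epithelial subunit, rose from 3 reads to 7.85 ± 5.21 CPM, and ITGA4 and ITGA7 fell (-1.85 ± 0.17 and -1.82 ± 0.21). ITGB6's log2 value of 7.46 was 10.53 without feeder-free replicate 1 and 6.79 without gel-3D replicate 3. Feeder-free replicate 1 held all 3 feeder-free reads of ITGB6, so the value of 10.53 rests on the fit's prior count.

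Stromal markers divided sharply. In the fibroblast list 4 genes were higher and 5 lower of 12 (camera adjusted p = 0.335). The proteoglycan LUM rose from 0.0538 to 121.6 ± 93.1 CPM, with 49.3, 89.0 and 226.6 CPM in gel-3D libraries 1, 2 and 3. DCN rose from 1 read to 12.8 ± 7.43 CPM and POSTN 4.19-fold, whereas COL1A1, chosen after its values were seen, was 4.40-fold lower. Without gel-3D replicate 3 the log2 values of LUM and COL3A1 were 10.24 rather than 11.04 and 9.10 rather than 9.95. Without feeder-free replicate 1 that of DCN was 11.24 rather than 9.44, and without feeder-free replicate 2 that of COL3A1 was 10.62. DCN's only feeder-free read lay in feeder-free replicate 1, so its value of 11.24 rests on the fit's prior count. In the mesenchymal transition list 8 of 17 genes were higher and 4 lower (0.196). Fibronectin, FN1, rose 14.6-fold to 2639 ± 317 CPM and SNAI2 to 23.5 CPM, while CDH2 and TAGLN fell (-1.68 ± 0.09 and -1.04 ± 0.11). VIM stood at 195 ± 25.3 and 271 ± 190 CPM (log2 0.47 ± 0.42, edgeR adjusted p = 0.364) and turned to -0.25 without gel-3D replicate 3. SNAI2's log2 value of 5.02 was 4.31 without that library.

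Protocadherins were lower in 32 of 70 cases and higher in 5. PCDH1 was 4.85-fold lower, PCDHB15 2.61-fold lower, and PCDHB1 at least 5.97-fold lower against 0 gel-3D reads, while PCDH10 rose 2.45-fold. The clustered alpha and gamma genes share 3' exons, which makes their single counts uncertain. Camera's adjusted p was 0.0376, the adjusted p = 0.839 with an estimated correlation, and the others ran from 0.00201 to 0.12. The call was lost without feeder-free replicate 2 (0.12, 20 lower), feeder-free replicate 3 (0.0685, 21 lower and 3 higher), gel-3D replicate 1 (0.0931) or gel-3D replicate 2 (0.0572).

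Other junction families had no camera call. Of 21 cadherins taken by symbol pattern, not all of them classical, 4 were higher and 10 lower (0.309). CDH10 rose to 50.7 CPM, and CDH13 and CDH23 were 5.97- and 2.40-fold lower. Of 13 claudins 3 were higher and 5 lower (0.965), with CLDN4 5.50-fold higher, CLDN1 5.86-fold lower and CLDN12 1.69-fold lower. Without feeder-free replicate 1 the lower claudins were 8 of 15 tested. Of 13 connexins 2 were higher and 8 lower (0.135), with GJA3, GJC3 and GJC1 lower (log2 -3.71 ± 0.41, -2.39 ± 0.34 and -0.56 ± 0.11) and GJD2 higher (2.47 ± 0.60). The lower connexins were 5, 4 and 5 without feeder-free replicate 2, feeder-free replicate 3 or gel-3D replicate 2, of 14, 14 and 15 tested. GJD2's log2 value was 1.80 without gel-3D replicate 3.

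Mechanosensitive YAP targets and actomyosin genes moved both ways, 7 higher and 5 lower of 20 (0.624). ANKRD1 rose to 19.5 CPM, AMOTL1 and TGFB2 had log2 fold changes of 2.09 ± 0.22 and 3.94 ± 0.48 (SE), and CYR61 fell (-1.88 ± 0.15). Without feeder-free replicate 1 ANKRD1's log2 value was 8.74 rather than 7.86, and without gel-3D replicate 3 that of TGFB2 was 3.32. Ion and water transport genes were 3 higher and 4 lower of 15 (0.859). The chloride channel CFTR fell (-3.90 ± 0.29), as did SCNN1A (-0.83 ± 0.12), while the carbonic anhydrases CA12 and CA2 rose 2.51- and 2.30-fold.

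Cell cycle genes leaned higher, with 14 of 25 up and 0 down, though 1 was lower without feeder-free replicate 1 and 2 without gel-3D replicate 1. CCNB1, a mitotic cyclin, rose 2.75-fold, CDK1 2.35-fold, and the nucleotide synthesis genes RRM2 and TYMS rose by log2 values of 1.14 ± 0.12 and 0.94 ± 0.11 (SE). With upper-quartile factors 10 were higher and 3 lower, and with library size alone 9 and 3. The higher genes were also 9 without feeder-free replicate 2, feeder-free replicate 3 or gel-3D replicate 2. By camera the adjusted p was 0.00387, the adjusted p = 0.748 with an estimated correlation, and the others ran from 0.000155 to 0.0243. None of the 14 was highest in gel-3D replicate 3.

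Ribosomal protein genes rose slightly, 60 of 77 against 1 lower, with a median log2 fold change of 0.44. The lower genes were 2 without gel-3D replicate 1, under DESeq2, with upper-quartile factors or with library size alone. The size of the rise depended on the scaling. With upper-quartile factors 45 were higher and the median was 0.31, and with library size alone 44 were higher and it was 0.28. RPL11, RPL7 and RPL23A rose 1.59-, 1.61- and 1.79-fold, and RPL26L1 1.65-fold. These genes held 4.80% ± 0.244 of gel-3D counts and 3.97% ± 0.211 of feeder-free counts (SD, n = 3; exact permutation p = 0.1). The camera adjusted p was 1.34e-06, the adjusted p = 0.748 with an estimated correlation, and the others ran from 1.02e-10 to 0.000106.

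Genes of the apoptosis and p53 list were higher in 8 of 15 cases and lower in 3. The cell cycle inhibitor CDKN1A rose from 7.18 to 73.4 CPM and BTG2 from 3.60 to 37.3 CPM, while the death receptor FAS fell from 26.8 to 1.98 CPM and SESN2 from 105.9 to 47.6 CPM. Camera's adjusted p was 0.0477, the adjusted p = 0.748 with an estimated correlation, and the others ran from 0.00642 to 0.223. The call was lost without feeder-free replicate 1 (0.0764), feeder-free replicate 2 (0.0677), gel-3D replicate 1 (0.116) or gel-3D replicate 2 (0.103).

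Glycolysis and low-oxygen genes went both ways, 7 higher and 6 lower of 21 (0.511). VEGFA and ADM, both secreted vascular factors, fell (log2 -2.89 ± 0.09 and -3.14 ± 0.19), while PKM and NDRG1 rose (1.14 ± 0.09 and 3.48 ± 0.39). Among immediate early and stress genes 6 were higher and 6 lower of 19 (0.687). The lower ones included CHAC1 and ATF3 (-3.63 ± 0.13 and -2.24 ± 0.14), and the higher ones HSPA1A and HSPA1B (2.20 ± 0.15 and 2.22 ± 0.14), near-identical genes whose reads are shared.

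Among 446 zinc finger genes 85 were higher and 124 lower (0.706), with ZNF440, ZNF436 and ZNF143 3.29-, 8.48- and 2.17-fold higher and ZNF649 2.24-fold lower. Of 31 histone genes 1 was higher, HIST1H1C (log2 1.09 ± 0.24), and 1 lower, HIST2H4A (-1.38 ± 0.47; 0.801 for the family). HIST2H4A no longer passed without feeder-free replicate 1 (log2 -0.65, adjusted p 0.08) or gel-3D replicate 2 (adjusted p 0.106). HIST1H2BH and HIST1H2BJ did not pass (edgeR adjusted p of 0.0645 and 0.108), though HIST1H2BH did without gel-3D replicate 3 (0.00239). The haemoglobin symbol pattern took in HBQ1 (adjusted p = 0.33) and HBEGF, a growth factor that is no globin and fell (-1.87 ± 0.31).

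Counts of list members were the same when adjusted over the list alone in 29 of the 37 lists and families. The exceptions, adjusted over the list alone, were 6 higher NODAL and ACTIVIN genes, 5 higher fibroblast genes, 7 higher and 23 lower collagens, 12 lower integrins and 9 lower connexins. There were also 63 higher ribosomal protein genes, 77 higher and 113 lower zinc finger genes, and 0 changed histone genes, of which 2 had passed over all genes.

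Among the 12 largest increases in expressed genes, the homeobox gene EVX1 rose from 1 read to 28.2 ± 1.82 CPM, a ratio of 2130 (95% counting interval 382 to 84300), and DLX5 and HOXB2 from 1 read each to 27.9 ± 16.7 and 19.4 CPM. C8orf4 rose from 0.0799 to 150.4 ± 114 CPM and ERP27, an endoplasmic reticulum protein, from 1 read to 19.2 ± 12.2 CPM. The largest decreases were led by CH25H, a sterol hydroxylase, which fell from 27.0 ± 3.93 CPM to 2 reads, a ratio of 936 (95% counting interval 259 to 7730). JAKMIP2-AS1, NPTX1 and TAC1 were 334-, 122- and 85.0-fold lower, the first an antisense transcript whose reads may include its partner's. INHBE, an activin subunit, fell from 136 ± 10.7 to 3.44 ± 1.54 CPM, and PAPLN from 49.97 ± 25.3 to 1.03 ± 0.326 CPM. SEZ6, C3orf72, SMOC2, HES3 and PIK3R6 were 53.8-, 53.9-, 33.7-, 33.2- and 34.9-fold lower. Without gel-3D replicate 1 the log2 values of SEZ6, PIK3R6 and DAZL were -6.93, -6.33 and -5.86 rather than -5.75, -5.12 and -5.11. Leaving out feeder-free replicate 1 gave 12.37 for DLX5, 11.84 for HOXB2 and 11.83 for ERP27, against 10.58, 10.05 and 10.03, and leaving out feeder-free replicate 2 gave 12.40 for EVX1 against 10.59. In each case the omitted library held the gene's only feeder-free read, so these higher values rest on the fit's prior count. Leaving out gel-3D replicate 3 gave 10.01 for C8orf4 against 10.81, 9.41 for ERP27 and 9.34 for HOXB2.

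The authors' deposited table listed 5432 genes higher and 5552 lower at a false discovery rate under 0.05. For 303 of the 16257 genes its log2 fold change lay over 0.1 from the value fitted to the counts beside the same symbol, after a median offset of -0.021. C1QBP is an example: it had 166 and 177 CPM and a fitted log2 value of 0.10, where the authors' deposited table gave 7.99. PARP1 had a fitted value of 0.50 and a value of -1.54 in the authors' deposited table, and C3orf72 had -5.75 and 0. Among symbols with no counts, 112 carried a fold change other than 0 in the authors' deposited table, and 112 symbols with counts carried exactly 0. Of genes called by both, 9384 had the same sign and 33 the opposite sign.

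**Figure D3:**
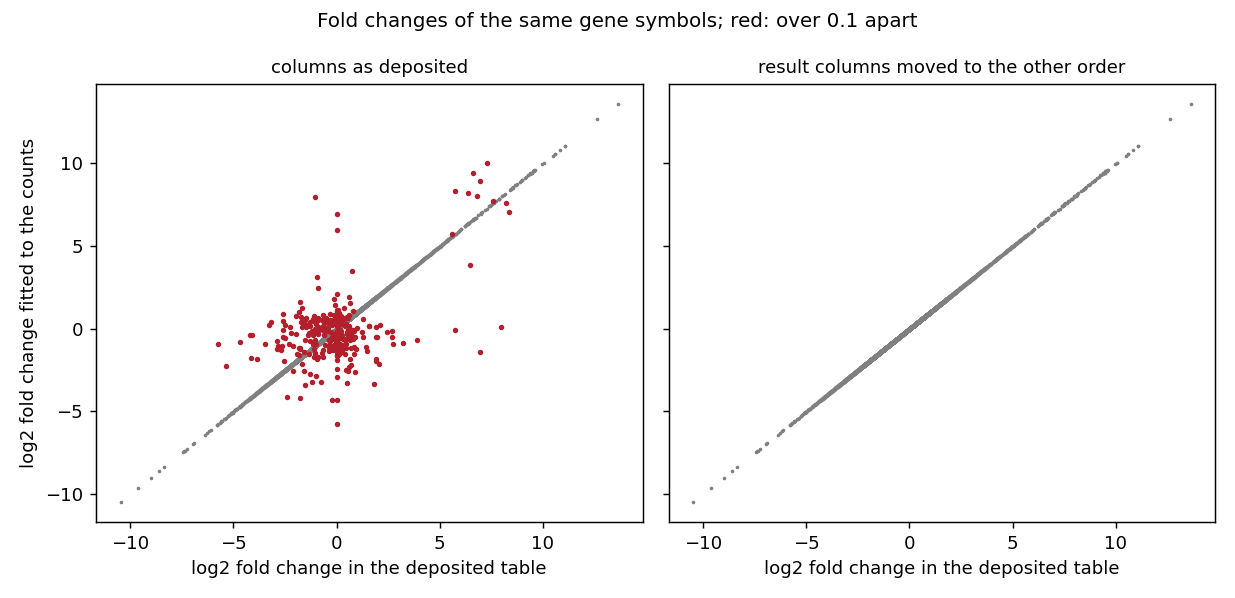
Log2 fold change fitted to the counts (vertical) against that in the authors' deposited table (horizontal) for each gene symbol, with red points over 0.1 apart after the median offset. On the left, with columns as deposited, 303 genes are red; on the right, with the result columns moved to a different alphabetical order, 0 are.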

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

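All alternatives in this part were set before the data were examined. No paired analysis was possible because replicate numbers were given in accession order and sample titles carry only library numbers. The planned settings for normalized values were not run, since the table holds counts. Counts of higher and lower genes stayed within 1.5 times of 4822 and 4843 under every setting run, from 3505 to 5083 and from 3465 to 5994. Genes called at least 2-fold lower numbered 920 under limma-voom and 857 at an adjusted p under 0.01, against 1404. The first cause was not tested and the second is the stricter threshold. Genes called both here and under a setting had opposite signs in 0 cases. Of 157 named genes past the threshold, 154 kept call and direction under all settings; CDH1, TFCP2L1 and HIST2H4A did not. POU5F1 turned to -0.01 with upper-quartile factors and -0.04 with library size alone, and ran from -0.02 to 0.32 with a library left out; VIM ran from -0.25 to 0.81. In simulated data with 200 changed genes few 1.5-fold changes were recovered; with as many called genes as here the adjusted threshold is less strict.

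No camera call among the lists and families fixed in advance held with an estimated correlation. Camera's adjusted p was then 0.387 for the amniotic, BMP, WNT pathway, mesoderm and HOX sets, 0.468 for surface ectoderm, keratins and WNT ligands, 0.554 for FGF ligands and 0.839 for protocadherins. It was 0.748 for the pluripotency, primed, trophoblast, simple epithelium, proliferation, apoptosis/p53, collagen and ribosomal protein sets. The estimate rests on 6 libraries. It was -0.037 for the WNT pathway and -0.044 for mesoderm genes, under the preset 0.01, so correlated members do not account for those lost calls. Fry does not compare a list's members with other genes, of which many changed here. Its adjusted p was under 0.05 for every set with a camera call except protocadherins (0.113). It was 0.00531 for the amniotic, 0.00329 for the BMP and 0.00106 for the HOX set. Some sets without a camera call also passed by fry. These were NODAL and ACTIVIN and connexins (both 0.00313), naive epiblast (0.0135), integrins (0.0179), haemoglobins (0.0328), endoderm (0.0364) and glycolysis (0.0466).

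Under limma-voom camera's adjusted p rose to 0.065 for primed epiblast, 0.344 for trophoblast, 0.0904 for WNT pathway, 0.114 for mesoderm and for simple epithelium, 0.223 for apoptosis/p53, 0.128 for WNT ligands and 0.108 for FGF ligands. Under DESeq2 it was 0.0763 for trophoblast and mesoderm and 0.0593 for apoptosis/p53 and FGF ligands. With the stricter low-count filter, which tests fewer genes, it was 0.234 for mesoderm, 0.084 for apoptosis/p53 and 0.0958 for protocadherins, while connexins reached 0.044. With no filter, FGF ligands had 0.0824. With upper-quartile factors apoptosis/p53, protocadherins and FGF ligands had 0.0631, 0.0846 and 0.0726, and with library size alone 0.0675, 0.086 and 0.0675. Outside the filters the cause was not tested.

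Directions that turned belonged to sets without a camera call. Claudins turned with upper-quartile factors (0.958), library size (0.979), the stricter filter (0.889) and DESeq2 (0.966). Histones turned under both scalings (0.958 and 0.906). Naive epiblast turned with no filter (0.94). Germ cell genes turned with the stricter filter (0.498), DESeq2 (0.966) and limma-voom (0.895), where glycolysis (0.911) and immediate early genes (0.895) turned too. Claudins also turned without feeder-free replicate 2 (0.933) or 3 (0.863). Naive epiblast, germ cell genes and histones turned without feeder-free replicate 1 (0.921 for each). Ion transport turned without feeder-free replicate 3 (0.98) or gel-3D replicate 2 (0.976). With each library left out, the adjusted p ran from 0.666 to 0.994 for naive epiblast, 0.693 to 0.921 for germ cell, 0.00642 to 0.116 for apoptosis/p53, 0.652 to 0.994 for ion transport, 0.00201 to 0.12 for protocadherins, 0.652 to 0.949 for claudins, 0.0232 to 0.0555 for FGF ligands and 0.629 to 0.951 for histones.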

Other observations

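The tests of the amniotic genes' mixture share, of the stromal genes, of the column order and of other splits were chosen after the result was seen. The mixture-share test replaced earlier versions on other gene sets, whose values had been seen and pointed the same way. The 3 gene lists in the next paragraphs were chosen after seeing the data, and genes that had prompted them were left out of their tests.

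Genes that the transcription factor ATF4 switches on under amino acid shortage or unfolded protein stress were lower in gel-3D. Of 30 tested, 24 were lower and 3 higher, with a median log2 fold change of -1.16, and medians of -1.32 to -1.01 under the other settings and with each library left out. The secreted factor STC2 fell from 598.5 to 74.0 CPM, the cystine transporter SLC7A11 from 358.5 to 56.8 CPM, the serine synthesis gene PSAT1 from 727 to 247 CPM, and ALDH1L2 from 47.4 to 2.04 CPM. PHGDH, SLC7A5 and ATF4 itself were the 3 that rose, against 1 without feeder-free replicate 2, feeder-free replicate 3 or gel-3D replicate 2, and 1 with upper-quartile factors or library size alone; ATF4 is regulated largely through its translation. Camera gave p = 2.51e-17 (7.53e-17 adjusted over 3 lists) and p = 0.0077 unadjusted with an estimated correlation. FGF21 is also in the FGF family above. The list's fall may reflect lower ATF4 activity in gel-3D or a stress in the feeder-free cultures, which the design cannot separate.

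Cholesterol synthesis and heat shock genes were higher in gel-3D. Of 24 tested targets of SREBP2, the sterol-sensing regulator, 16 were higher and 2 lower (median log2 0.52; 0.35 to 0.61 under the other settings). HMGCS1 rose from 269 to 967 CPM and IDI1 from 37.2 to 123 CPM. Camera gave p = 3.06e-06 (4.59e-06 adjusted) and p = 0.155 with an estimated correlation. Of 19 heat shock genes 13 were higher and 1 lower (median 0.60; 0.44 to 0.67 under the other settings), and 0 were lower without feeder-free replicate 1 or 2 or gel-3D replicate 2 or 3 by edgeR. HSPA8 rose from 452 to 1485 CPM. Camera gave p = 0.000122 (0.000122 adjusted) and p = 0.0996 with an estimated correlation. Both tests are consistent with raised sterol synthesis and chaperone genes, as hypotheses formed on these data.

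Gel-3D replicate 3 lay further from feeder-free cells than its partners. Sequencing depth is argued against: thinning all libraries to the smallest total kept 97.9% of the gap on the first component, 39.1 of 39.9. Feeder-free-like cells in replicate 1 could dilute its amniotic genes, but these would need a median share of 64.3% (17.8 to 83.5% over 24 genes), and of 1400 genes at or under 50% of their feeder-free level in replicate 3, chosen without replicate 1, 79.7% lay below that share in replicate 1. The 639 genes called at least 2-fold lower alone need 10.9%, with 7.4% of them below it, between the bounds set beforehand. A small mixture for those genes therefore cannot be told apart from cells that have moved less far. No biological explanation was tested, since the labels give replicates no other difference.

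LUM, DCN and COL3A1 rose while most stromal genes did not. Stray stromal cells could bring them, but the other 9 members had a median log2 fold change of -0.48. Between gel-3D replicates 3 and 1 these members differed by a median log2 ratio of 0.22, against 2.20 for LUM. COL1A1 stood at 57.4 and 91.0 CPM in replicates 1 and 3, where LUM stood at 49.3 and 226.6 CPM. As 8 of the 9 members had at least 10 CPM in feeder-free cells, a small stromal share cannot be told apart from expression in the amnion-like cells. POSTN, the member below that level, rose from 0.984 to 4.14 CPM, while 5 genes of the stromal list were lower. It stood at 4.44, 3.76 and 4.21 CPM in gel-3D libraries 1, 2 and 3.

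In the authors' deposited table the mismatched result columns could come from sorting. Moving the result columns of the authors' deposited table between plain character order and an order that ignores case and punctuation left 0 of 303 genes over 0.1 apart, and calls shared with the fit had the same sign in 9511 cases and the opposite sign in 0. That the names belong to the result columns is argued against: among moved symbols, protein-coding names had log2 CPM values above non-coding names by 2.70 beside the deposited counts and 1.49 when moved, a difference of 1.2 (bootstrap 95% 0.67 to 1.74). Among symbols of the authors' deposited table, 793 change place and 337 change call or sign. SOX21 is an example: -1.76 in the authors' deposited table, -4.16 after moving and -4.18 in the fit.

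The real split of the 6 libraries called 9665 genes with edgeR, and the highest of the other 9 splits called 0, with 1 to 649 genes at an unadjusted p under 0.05. With 1 of 10 splits as large, the splits are too few for a share under 0.05. Each of the other splits also put libraries of both culture systems in both groups. The difference between the systems then counted as spread within groups, so their 0 calls say little about chance.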
